A study of Mus musculus with 2 samples.

How the data were processed

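RNA was measured in 2 libraries of cultured mouse bone marrow derived macrophages of the FVB strain, 1 labelled WT and 1 labelled RON TK-/-. Per the labels, total RNA was isolated with TRIZOL, libraries were made with a TruSeq RNA kit and sequenced as single reads of 50 bases, and both libraries ran in the same sequencing run and lane. Strand use is not given in the sources used here, so genes that overlap on opposite strands cannot be told apart.

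The authors deposited 1 table per library with FPKM values per RefSeq transcript, and the column names are those that Cufflinks writes, per the file headers. The deposited coverage column gives the mean read depth per base of each transcript, per the file headers. The submitters' processing notes name the build mm10 and the program DESeq, without a version or role. The aligner and the annotation release are not given in the sources used here. Each table held 31580 rows with 31517 transcript identifiers and 23444 gene symbols, and all rows had the status OK. Coverage divided by FPKM was nearly constant within a file (median 2.99 in the library labelled WT and 3.36 in the library labelled RON TK-/-), which at 50 bases per read implies about 59800000 and 67100000 reads. Estimated reads per gene, as coverage times length over read length, summed to about 54200000 and 61900000. These are estimates, not counts, and no count model was used. Total FPKM was 426617 and 446327, the upper quartile of rows was 3.68 and 5.71 FPKM, and 9982 and 10911 genes had at least 1 FPKM. The 100 most abundant genes took 28.2% and 24.9% of estimated reads.

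Zeros were checked, since an exact 0 in such a table can be a failed estimate. Of 189 genes of housekeeping families 5 were at 0 in a library, and these were Y-linked or tissue-restricted members of the families. Even so, genes at 0 are described only as listed at 0, and no fold is given against them. There were 16 genes at 0 in a library with at least 20 FPKM in the other. Their log2 ratios depend on the pseudocount. Locus starts in the files matched the RefSeq table of the same assembly (GRCm38) with an offset of 1 for 12704 genes and of 0 for 725, so starts were taken as counted from 0 and are printed counted from 1.

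Rows of a gene symbol were summed. The ratio of a gene was log2 of (FPKM + 1) in the library labelled RON TK-/- over (FPKM + 1) in the library labelled WT, with a pseudocount of 1. Genes with at least 1 FPKM in either library were taken as detected, and a difference of 2-fold on that scale was counted. No test was possible with 1 library per group. Values were used as deposited, and the median ratio of detected genes is printed so that each value can be read against it.

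The 49 gene lists, the alternatives and the rule for named genes were set before the data were examined, apart from the additions stated here and in the closing section. The rule named Mst1r, the 12 highest and 12 lowest ratios among genes with at least 5 FPKM in a library (without small RNAs and clone-like, Gm, LOC and Rik symbols), up to 4 detected members per list with the largest absolute ratio, and Arg1, Retnla, Chil3, Mrc1, Nos2, Il1b and Tnf. The 1201 list entries gave 1162 members found in the files, once entries naming the same gene within a list were merged. Another symbol was used for 10 entries, and some of these named a gene already in the list. For each list with at least 5 detected members, the median ratio was placed among the medians of 10000 random lists (seed 1) drawn from the same 20 bins of mean expression, and called apart outside the middle 95% of them. Under the alternatives 2000 random lists were drawn.

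The procedure was tested on simulated data, in which a copy of the library labelled WT with 10077 genes carried planted differences. Of the planted genes, 100% were past 2-fold at a true fold of 3 or 8 and 0% at 1.5, and 0.0102% of unchanged genes were. A planted list of 25 genes without a shift lay at percentile 7.21, and lists shifted by 0.5 or 1 lay at percentile 100. The simulation holds counting noise and a small random spread of each gene's level, not the differences between animals or cultures, which these data cannot give. Its results therefore do not show how well a shift of a list would be found in the real libraries.

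Alternatives were pseudocounts of 0.1 and 5, no filter or a minimum of 5 FPKM, rescaling to a median ratio of 0 or to TPM, the most abundant row of each gene only, thresholds of 1.5-fold and 4-fold, and leaving out small RNA, ribosomal protein, mitochondrial and haemoglobin genes. Estimated reads scaled to library totals, and median rescaling with a 4-fold threshold, were added after seeing the data. The design set the list median and its percentile, but not how a list's value should be compared between settings. It was first taken relative to the median of all detected genes, then, after its results were seen, also relative to matched random lists and as deposited. The first form is used for the calls in the closing section, and the outcome of all 3 is printed there. Calculations used Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9. Results for some genes are not reported here.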

Results

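The series holds RNA-seq of bone marrow derived macrophages, cells grown in culture from marrow precursors, of the inbred mouse strain FVB. There were 2 libraries, 1 per group. The first was labelled wild type (WT, RON proficient) and the second RON TK-/-, in which the tyrosine kinase of RON is deficient. RON, the product of Mst1r, is a cell surface receptor of macrophages whose ligand is macrophage stimulating protein. Both labels state that the cells had received recombinant interleukin-4 at 10 ng/mL for 72 hours, a cytokine that drives alternative (M2) activation of macrophages. The comparison asks how gene expression differs between interleukin-4 treated macrophages with and without the RON kinase. Each file lists 31580 transcript rows of 23444 gene symbols as FPKM (fragments per kilobase of transcript, scaled to the depth of the library) with the mean coverage. The coverage implied about 59800000 reads for the library labelled WT and about 67100000 for the library labelled RON TK-/-. With 1 library per group there is no replicate check of any difference, so no test was run and no p-value is given. A value given as higher or lower compares these 2 libraries, not the conditions.

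The targeted gene was examined first. Mst1r lies on chromosome 9 from 107906889 to 107920383 of the mm10 build, and its listed transcript is 4706 bases long. It was listed at 0 FPKM in the library labelled WT and at 0 FPKM in the library labelled RON TK-/-. At the implied depths 3 reads would have given 0.0107 and 0.00949 FPKM, limits that cover counting error only. Mst1r therefore checked neither label. Other members of the RON receptor list were detected for 3 of 10 genes. The related receptor Met had 8.03 FPKM in the library labelled WT and 0.85 in the library labelled RON TK-/-, Plxnb2 had 40.7 and 63.0, and the Met ligand Hgf had 3.40 and 3.33.

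The libraries had opposite activation profiles. Arg1, Chil3 and Retnla, marker genes of a response to interleukin-4, were abundant in the library labelled RON TK-/- and at or near 0 in the library labelled WT. Arg1, the arginase of alternatively activated macrophages, had 5041 FPKM in the former and 1.0 in the latter, a log2 ratio of 11.30. The chitinase-like Chil3 had 4604 FPKM and the secreted protein Retnla 3665 FPKM in the library labelled RON TK-/-, and both were listed at 0 in the library labelled WT. The marker Mrc1 was also higher in the library labelled RON TK-/- (1016 FPKM) but was not near 0 in the library labelled WT (71.2 FPKM). In the alternative activation list below, 4 members were at least 2-fold higher in the library labelled WT. Inflammatory genes were mostly higher in the library labelled WT. Cxcl10, an interferon-induced chemokine, had 4711 FPKM in the library labelled WT against 0.23, Tnf had 1262 against 0.52, Il1b had 823 against 0.20 and Nos2, the inducible nitric oxide synthase, had 1100 against 3.63. Arg1, Chil3 and Retnla were thus at or near 0 in a library whose label states treatment with interleukin-4, and each direction below rests on the labels as deposited. Genotype and library cannot be separated in this design.

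**Figure D1:**
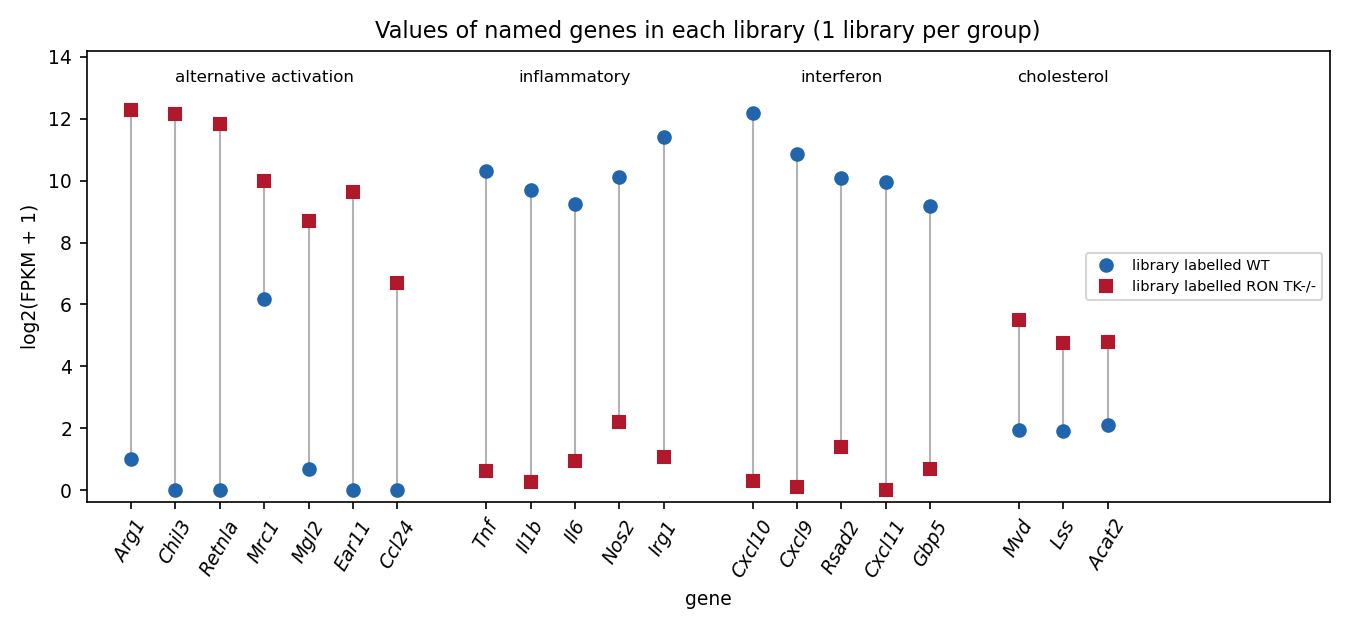
Values of named genes in the library labelled WT (circles) and the library labelled RON TK-/- (squares), as log2(FPKM + 1) on the vertical axis, with genes grouped on the horizontal axis and 1 library per group, so without error bars. Chil3, Retnla, Ear11 and Ccl24 sit at 0 in the library labelled WT, and Cxcl11 sits at 0 in the library labelled RON TK-/-.

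Of 11288 genes with at least 1 FPKM in either library, 2890 (25.6%) were at least 2-fold higher and 983 (8.71%) at least 2-fold lower in the library labelled RON TK-/-, on the scale of FPKM + 1. That scale understates differences of low genes. The median log2 ratio of all detected genes was 0.57 above 0, and the split depended on it. Higher genes made up 74.6% of the genes apart by 2-fold with the values as deposited and 43.3% (1272 higher, 1669 lower) once the libraries were rescaled to a median ratio of 0. Large differences lay mostly on the other side, with 99 genes at least 8-fold higher and 230 at least 8-fold lower, and 12 and 44 genes beyond 64-fold. These counts include genes listed at 0 in a library, such as Chil3 and Cxcl11, whose ratios depend on the pseudocount. Across the 9605 genes with at least 1 FPKM in both libraries, Pearson's r of log2 FPKM was 0.80 and Spearman's rho 0.79, computed across genes, which are not independent replicates.

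**Figure D2:**
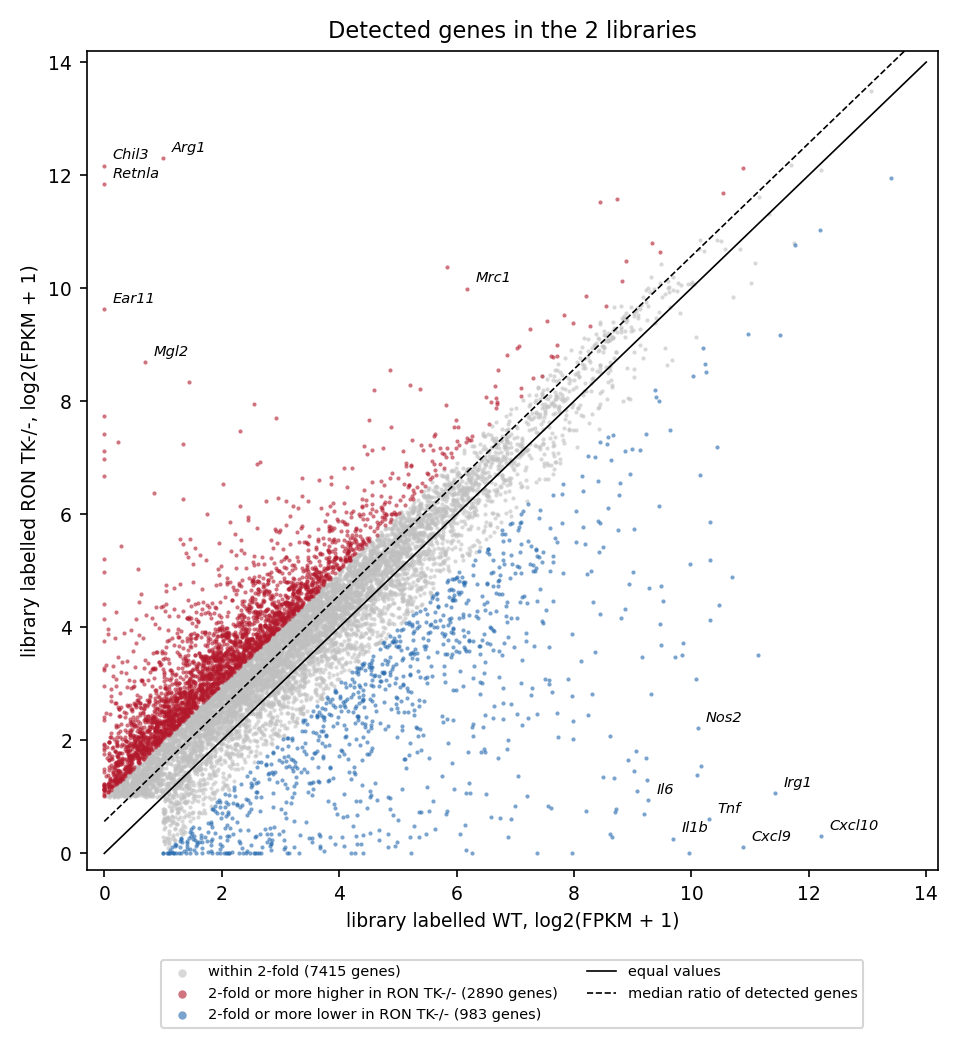
Each point is 1 of 11288 detected genes, with log2(FPKM + 1) of the library labelled WT on the horizontal axis and of the library labelled RON TK-/- on the vertical axis, and colours mark the 2890 genes at least 2-fold higher and 983 at least 2-fold lower. The solid line marks equal values and the dashed line the median log2 ratio of 0.57, and the named inflammatory genes lie at the lower right, far from both lines.

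The 12 genes highest in the library labelled RON TK-/- relative to the library labelled WT were Chil3, Retnla, Arg1, Ear11, Mgl2, Chil4, Msx3, Cldn11, Tmem26, Rbp4, Ccl24 and Cbr2. Ear11, a secreted ribonuclease, had 794 FPKM, Chil4 had 211, the homeobox gene Msx3 had 169, the tight junction gene Cldn11 had 138 and the eosinophil chemokine Ccl24 had 101, and all 5 were listed at 0 in the library labelled WT. The lectin Mgl2 had 411 FPKM against 0.62 in the library labelled WT, Tmem26 had 154 against 0.18, the retinol carrier Rbp4 had 323 against 1.73, and the carbonyl reductase Cbr2 had 151 against 1.53. Chil3 spans 106147554 to 106167564 and Chil4 106201491 to 106219479 on chromosome 3, Retnla 48842552 to 48844461 on chromosome 16, and Arg1 24915207 to 24927470 on chromosome 10. The Ear and Chil families hold near-identical copies between which reads could have been split, so their single values are uncertain.

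The 12 genes lowest in the library labelled RON TK-/- were Cxcl10, Cxcl9, Irg1, Cxcl11, Tnf, Il1b, Rsad2, Ccrl2, Gbp5, Gbp4, Il6 and Cd69. Cxcl9, Cxcl10 and Cxcl11, chemokines that bind the receptor CXCR3, are neighbours on chromosome 5 between 92321331 and 92363296. Cxcl9 had 1879 FPKM in the library labelled WT and 0.08 in the library labelled RON TK-/-, and Cxcl11 had 999 FPKM in the former and was listed at 0 in the latter. Irg1 (also named Acod1), which makes itaconate, had 2746 FPKM against 1.10, a log2 ratio of -10.36. The antiviral gene Rsad2 had 1092 against 1.63, the chemerin receptor Ccrl2 1139 against 1.91, the cytokine Il6 611 against 0.92 and the activation marker Cd69 392 against 0.27. The guanylate binding proteins Gbp5 and Gbp4 had 584 and 399 FPKM against 0.61 and 0.23, and they belong to a family of similar copies with the same uncertainty.

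Gene lists were compared with 10000 random lists of equal size and matched mean expression, as a description of these libraries. Of 49 lists, 41 had at least 5 detected members, and 10 lay above and 15 below the middle 95% of their random lists, where 2.05 would be expected by chance if members of a list varied independently. Members of a list can vary together, and some genes sit in several lists. The median of matched random lists was above 0 because the median of all detected genes was 0.57. Counts of genes at least 2-fold higher and lower relative to that median are given below as centred counts, the higher genes first.

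The alternative activation list was higher in the library labelled RON TK-/-, with a median log2 ratio of 2.25 at percentile 100. Of 34 detected members, 19 were at least 2-fold higher and 4 at least 2-fold lower. The centred counts were 18 and 7. Chil3, Retnla and Arg1 led the list, and the mannose receptor Mrc1 had 1016 FPKM against 71.2 in the library labelled WT. Here and below, members that complete a count of 5 or fewer were named after their values were seen. The 4 exceptions were the chemokines Ccl22 (53.2 FPKM in the library labelled WT, 4.03 in the other) and Ccl17 (10.4 and 1.37), the transglutaminase Tgm2 (282 and 84.1) and the receptor subunit Il13ra1 (37.2 and 10.8).

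Classical activation genes were lower almost throughout. Of 35 detected members 33 were at least 2-fold lower in the library labelled RON TK-/- and 0 at least 2-fold higher (centred 0 and 34), and the median log2 ratio was -5.22 at percentile 0. Irg1, Tnf, Il1b and Il6 led this list. The remaining 2 members were the cystine transporter Slc7a11 (7.30 FPKM in the library labelled WT and 3.28 in the other) and the costimulatory gene Cd80 (11.7 and 16.7).

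Interferon genes had the same order. In the type I interferon list 34 of 37 detected genes were at least 2-fold lower and 0 higher (centred 0 and 36), with a median of -3.35 at percentile 0. Cmpk2 had 601 FPKM in the library labelled WT against 2.24 and Ifit2 had 486 against 2.13, and the 3 genes within 2-fold were Irf9, Bst2 and Ifi27l2a. In the interferon gamma list 26 of 27 were at least 2-fold lower and 0 higher (centred 0 and 27), with a median of -5.40 at percentile 0, and Cxcl9, Cxcl11, Gbp5 and Gbp4 led it. The gene within 2-fold was Ido1, with 1.28 against 0.17. It was lower too, and counts as within 2-fold only because 1 is added to such low values.

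Antigen presentation lists were lower by less. For MHC class I the median was -1.01 at percentile 0.01, with 8 of 16 genes at least 2-fold lower and 0 higher (centred 0 and 12). H2-Q4 had 191 FPKM in the library labelled WT against 30.7 and the peptide loading factor Tapbp 222 against 81.3, although H2-Q genes are similar copies and their values are uncertain. The MHC class II list had a median of -0.17 at percentile 1.03, with 3 of 11 genes lower and 1 higher (centred 0 and 4). Ciita, the master regulator of class II genes, had 24.5 against 0.34 and H2-Ab1 10.7 against 1.41, while the protease gene Ctss had 641 against 1780. With only genes of at least 5 FPKM this list was no longer apart (percentile 30.8). Its median as deposited was then 0.41, so the sign of that median depended on the minimum. Relative to the median of all genes used, the list stayed negative, at -0.13.

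Chemokines and their receptors had a median of -2.34 at percentile 0, with 17 of 29 genes at least 2-fold lower and 6 higher in the library labelled RON TK-/- (centred 6 and 20). Cxcl10, Cxcl9, Cxcl11 and Ccrl2 led the list. Toll-like and inflammasome receptors had a median of -0.49 at percentile 0, with 13 of 32 genes lower and 8 higher (centred 3 and 16). The inflammasome sensor Nlrp3 had 146 FPKM in the library labelled WT against 1.03, Tlr2 had 211 against 3.18 and the endotoxin co-receptor Cd14 had 1010 against 33.7, while Tlr4 had 5.72 against 73.8. The complement list had a median of -0.20 at percentile 0.42, with 4 of 17 genes lower and 2 higher (centred 2 and 7). Complement factors Cfb (52.7 against 1.57) and C3 (342 against 39.4), together with C1s and C2, were lower, and the integrin subunits Itgax (2.89 against 29.5) and Itgam (61.0 against 185) higher.

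Genes of cholesterol and fatty acid synthesis, the amino acid response and ER stress were higher in the library labelled RON TK-/-. In cholesterol biosynthesis 22 of 24 genes were at least 2-fold higher and 0 lower, with a median log2 ratio of 2.12 at percentile 100. The other 2 were Ebp and the regulator Srebf2. The centred counts were 16 and 0. Mvd had 2.87 FPKM in the library labelled WT against 43.8, Lss 2.73 against 25.8 and Acat2 3.26 against 26.3. The amino acid response list of ATF4 targets had 17 of 28 genes higher and 1 lower (centred 13 and 2), with a median of 1.44 at percentile 100. Chac1 had 1.04 against 18.6, Atf5 20.5 against 147 and Phgdh, the first enzyme of serine synthesis, 6.94 against 52.1, and the lower gene was the tryptophanyl-tRNA synthetase gene Wars (78.2 against 35.3). The ER stress list had 11 of 23 genes higher and 1 lower (centred 6 and 1), with a median of 0.95 at percentile 100. It shares Chac1, Ddit3 and Trib3 with the ATF4 list. Its Ddit3 had 6.48 against 52.7 and the ER chaperone Pdia4 40.6 against 295, and the lower gene was the phosphatase subunit Ppp1r15a (64.5 against 12.3). The fatty acid synthesis list had 8 of 16 genes higher and 1 lower (centred 5 and 1), with a median of 1.06 at percentile 99.4. Fasn, the fatty acid synthase, had 3.25 against 28.5 and Fads2 1.73 against 17.3, while the acyl-CoA synthetase Acsl1 had 158 against 11.8. Fatty acid synthesis passed to percentile 97.45, just inside the limit, with a pseudocount of 0.1.

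Both mitochondrial lists had a median difference of under 2-fold, although some members of the first lay further apart. The tricarboxylic acid cycle and glutamine list had 7 of 24 genes at least 2-fold higher and 0 lower (centred 5 and 0), with a median of 0.82 at percentile 99.95. Gpt2 had 1.36 FPKM in the library labelled WT against 13.9 and the cytosolic isocitrate dehydrogenase Idh1 21.2 against 132. Nuclear genes of the respiratory chain lay above matched random lists (median 0.61, percentile 99.95), yet 0 of 39 were at least 2-fold apart (centred 0 and 0). Their median was 0.04 above that of all detected genes, and this sign turned with median rescaling, TPM rescaling and a pseudocount of 0.1. Ribosomal protein genes had a median of 0.56 at percentile 100, with 1 of 50 genes, Rpl26, at least 2-fold higher (centred 1 and 0). Relative to all detected genes they were at -0.0037, and the sign turned with a pseudocount of 5, without a filter and with a 5 FPKM minimum. After median rescaling the median itself was -0.024 for the respiratory chain and -0.080 for ribosomal proteins.

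Genes of S phase and mitosis were higher for 18 of 40 members and lower for 0, with a median of 0.86 at percentile 98.9. The centred counts were 7 and 2. The mitotic kinesin Kif20a had 2.41 FPKM in the library labelled WT against 12.8 and the kinases Aurka and Plk1 2.41 and 2.82 against 12.2 and 13.4. With a 5 FPKM minimum this list lay inside the limits (percentile 94.1). The p53 target list had 11 of 25 genes higher and 4 lower (centred 7 and 5), with a median of 0.89 at percentile 99.0, and it lay inside the limits after median rescaling (94.9) or TPM rescaling (96.2). Its members went both ways, with Sesn1 at 0.76 against 16.9 and Gadd45b at 189 against 7.38. The other 3 lower genes were Btg2, Cdkn1a and Mdm2.

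Tumour-promoting secreted factors had a median of -0.33 at percentile 0, with 13 of 39 genes at least 2-fold lower and 5 higher (centred 4 and 19). Il1rn, which encodes the interleukin-1 receptor antagonist, had 1269 FPKM in the library labelled WT against 35.4, Pdgfb 60.8 against 1.21, Lif 76.6 against 3.89 and the collagenase Mmp13 1133 against 102. The 5 higher genes were Igf1, Mmp19, Timp2, Fn1 and Adam8. Immediate early genes had a median of -0.71 at percentile 0, with 13 of 28 lower and 5 higher (centred 3 and 16). The phosphatase Dusp2 had 37.5 against 0.40 and Zfp36, which destabilises cytokine mRNAs, 223 against 30.0, and the 5 higher genes were Klf2, Dusp4, Myc, Jun and Dusp6. The NRF2 list had a median of -0.14 at percentile 0.35, with 6 of 25 lower and 0 higher (centred 0 and 10). Sod2, the mitochondrial superoxide dismutase and also an inflammatory target gene, had 348 against 17.7 and Sqstm1 796 against 179.

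For 2 of the lists that stood apart the raw median and the position among random lists differed in sign. Scavenger receptors had a median of 0.07 at percentile 2.23, with 6 of 29 genes at least 2-fold lower and 5 higher (centred 3 and 7). The phosphatidylserine receptor Timd4 had 16.0 FPKM in the library labelled WT against 0.09, the Fc receptor Fcgr1 26.6 against 3.58 and the integrin subunit Itgb3 3.93 against 26.5, and Cd36, Fcgr2b, Cd163 and Cd300a were also at least 2-fold higher. Extracellular matrix genes and receptors had a median of 0.15 at percentile 1.82, with 3 of 32 lower and 5 higher (centred 4 and 8). The integrin subunits Itga4 and Itga5 had 72.6 and 163 against 2.48 and 32.1, while the collagen genes Col6a2 and Col3a1 had 16.0 and 48.5 against 72.8 and 171. The other members apart by 2-fold were Ddr1, which was lower, and Fn1, Col6a1 and Col6a3, which were higher. Scavenger receptors passed to percentile 2.83 without a filter and 2.85 with a 5 FPKM minimum, and the matrix list to 2.75 with that minimum. After median rescaling both medians were below 0, at -0.57 and -0.46.

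The other pathway lists lay between the limits. PPAR targets and fatty acid oxidation were at percentile 97.48, just inside, with a median of 0.70 and 8 of 23 genes higher and 0 lower (centred 4 and 1), and all 7 alternatives put this list above the limit. Pparg had 2.92 FPKM in the library labelled WT against 26.2 and Cd36 104 against 376. LXR targets had a median of 0.49 (percentile 67.8), in which the desaturase gene Scd2 had 4.87 against 245. Glycolysis had 0.29 (33.3), hypoxia response 0.48 (78.55), lysosome and phagosome 0.25 (31.6), heat shock 0.76 (95.4), eicosanoid enzymes 0.56 (65.9), iron handling 0.46 (61.1), signalling feedback genes 0.31 (13.5) and histones 0.61 (43.7). Some of these held members far apart in both directions. Ptgs2, the inducible cyclooxygenase, had 1079 FPKM in the library labelled WT against 7.51, the transferrin receptor Tfrc had 21.7 against 201, the protease Ctsl 424 against 3043 and Socs3 515 against 30.7. Mitochondrially encoded genes had 0 of 28 symbols in the files.

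**Figure D3:**
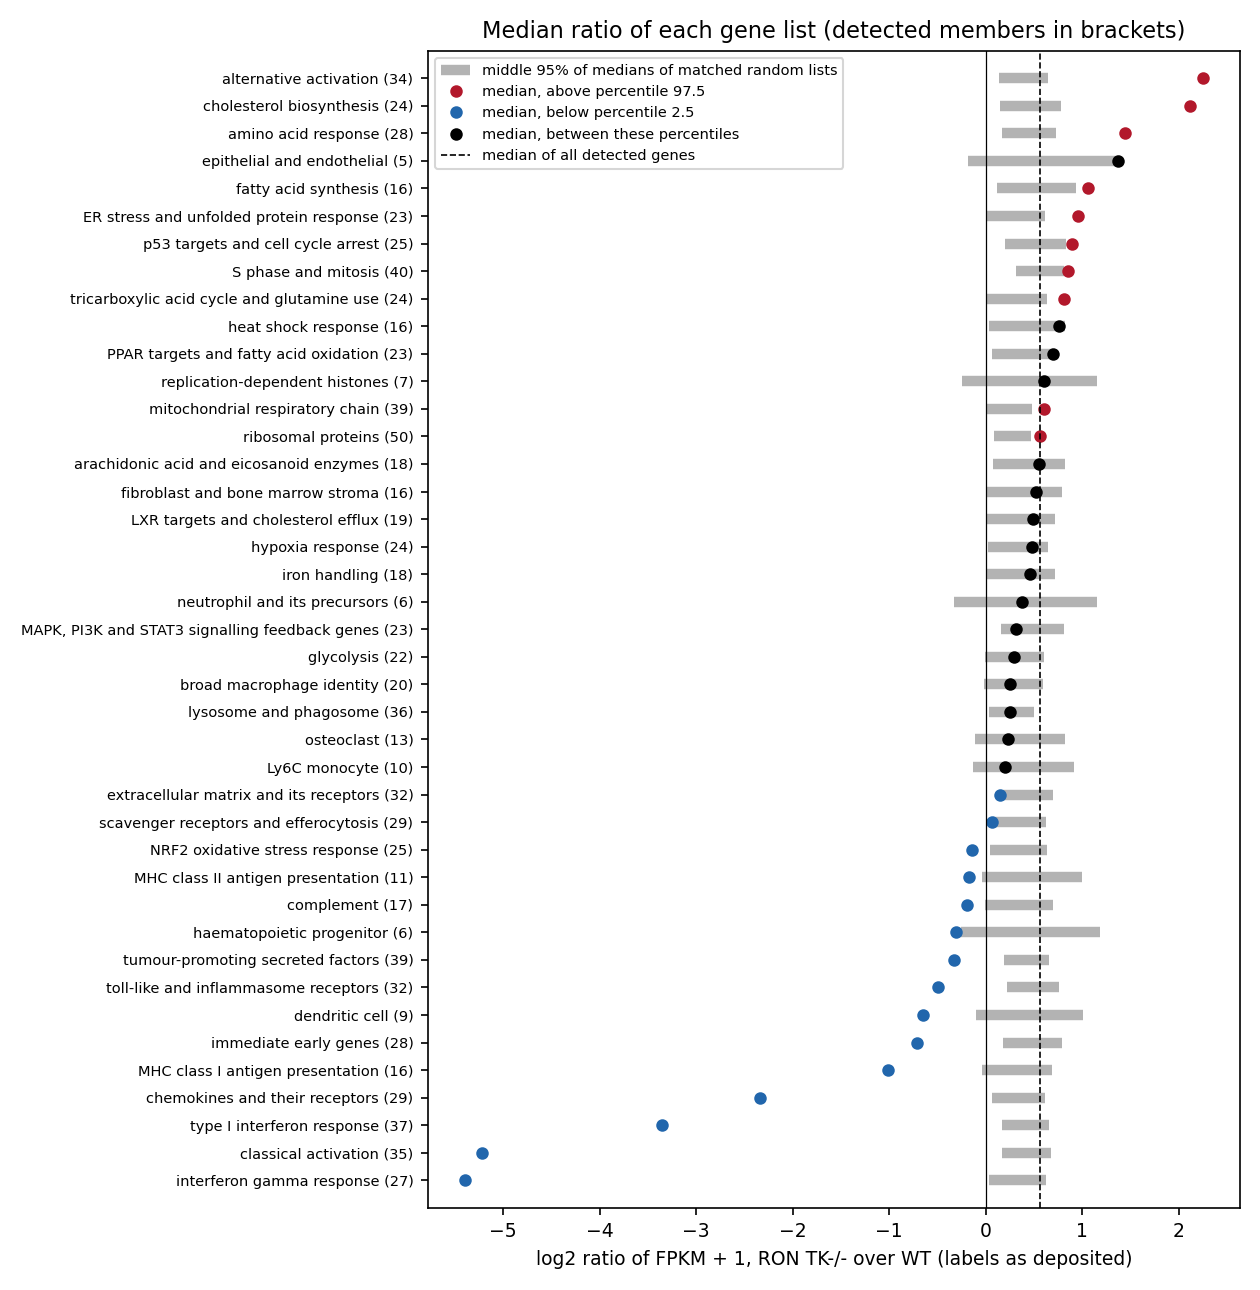
Median log2 ratio (RON TK-/- over WT as labelled, horizontal axis) of the 41 gene lists with at least 5 detected members, shown as points with the number of members in brackets, and grey bars for the middle 95% of medians of matched random lists. The interferon gamma (-5.40) and classical activation (-5.22) lists lie farthest to the left and the alternative activation (2.25) and cholesterol (2.12) lists farthest to the right of the dashed line, which marks the median of all detected genes.

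Both libraries expressed general macrophage genes. The broad macrophage list was within matched random lists (median 0.26, percentile 27.8), with 5 of 20 genes higher and 5 lower (Cd14, Fcgr1, Cebpb, Mertk and Spi1), and centred counts of 4 and 8. The lysozyme gene Lyz2, named after its values were seen, had 3317 FPKM in the library labelled WT and 4651 in the library labelled RON TK-/-. The transcription factor gene Cebpa (2.11 against 38.0) was higher in the library labelled RON TK-/-. Lists of Ly6C monocytes (median 0.20, percentile 15.1), neutrophils (0.38, 29.0), osteoclasts (0.24, 18.2), stroma (0.52, 67.3) and epithelial or endothelial cells (1.38, 97.2) did not stand apart. Dendritic cell markers (-0.65, percentile 0.19) and progenitor markers (-0.31, 2.08) were lower. In the dendritic list 3 of 9 detected genes were at least 2-fold lower and 1, Itgax, higher (centred 1 and 5). Its Ccl22 and Ccl17 are also interleukin-4 genes, and Fscn1 had 73.2 against 12.7. In the progenitor list only Procr was at least 2-fold apart among 6 detected genes (40.1 against 5.55; centred counts 0 and 3), and the list passed to percentile 2.6 with a pseudocount of 5 and 4.4 after median rescaling. Too few markers were detected for a percentile in T and NK cells (3 of 17 measured), B cells (4 of 15), mast cells and basophils (3 of 19), eosinophils (2 of 11) and erythroid cells and megakaryocytes (2 of 19). Among them were Il6 and the histidine decarboxylase gene Hdc (12.4 against 0.03), which activated macrophages also express, and the platelet gene Vwf (4.22 against 38.6). Xist had 43.7 and 57.1 FPKM, and 4 Y-linked genes were listed at 0 in both libraries.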

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

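Each library is the only member of its group, so no replicate could be left out and the doubt about the library labelled WT could not be tested by removing it. The thresholds and scalings were planned, except the median rescaling with a 4-fold threshold and the estimated reads scaled to library totals, which were chosen after seeing the data. The 2890 higher genes became 983 with a pseudocount of 5, 1272 after median rescaling, 5519 at 1.5-fold, 419 at 4-fold and 225 with median rescaling and 4-fold. The 983 lower genes became 1669 after median rescaling and 463 at 4-fold. The other count alternatives stayed within 1.5 times the values reported. Higher genes were 74.6% of those apart as deposited and 58.7% with a pseudocount of 5. They were 43.3% after median rescaling, 47.5% at 4-fold and 24.0% with both. A stricter threshold lowers a count by construction, and median rescaling multiplies all values of the library labelled WT by 1.56. Of 153 named genes at least 2-fold apart, 144 stayed so in the same direction after median rescaling and 143 with a pseudocount of 5. None of these 153 turned sign in the alternatives run on them.

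List medians are given here relative to the median of all genes used. Of 283 values, 8 turned sign in lists that stood apart, and of the others 226 moved by at most 0.5 times the width of the random range and 49 by more. In lists that did not stand apart 22 values turned, 9 of them among the 49. As deposited, 51 moved by more, and 5 turned in lists that stood apart and 11 in the other lists. Relative to matched random lists, a form computed after the first was seen, 21 moved by more and these numbers were 0 and 5, so the number of turned signs depends on the reference chosen. Of 25 lists that stood apart, 18 did so in all 7 alternatives, and the 7 others are named with their percentiles in the report. Heat shock genes passed the limit with a pseudocount of 5 (percentile 99.2) and with the most abundant row of each gene only (97.75), and epithelial and endothelial markers with a pseudocount of 0.1 (98.1) and with TPM (99.4). With a 5 FPKM minimum the histone, neutrophil, epithelial and progenitor lists had too few members for a value. Among lists that stood apart, signs turned for the respiratory chain with a pseudocount of 0.1 (-0.035), median rescaling (-0.024) and TPM (-0.00064), and for ribosomal proteins with a pseudocount of 5 (0.18) and a 5 FPKM minimum (0.021). Among the other lists, and apart from the setting without a filter, signs turned for LXR targets (pseudocount of 5 and 5 FPKM minimum), hypoxia, iron handling and histones (pseudocount of 5), neutrophils (pseudocount of 0.1) and eicosanoid enzymes (all but the most abundant row).

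Without a filter the reference is 0, because most of the 23444 genes are then at or near 0 in both libraries, and undetected members also enter (37 rather than 34 genes of the alternative activation list, 35 rather than 29 of the chemokine list). With reference and members altered together the values became 1.32 for alternative activation, -5.22 for classical activation, -3.34 and -5.40 for type I interferon and interferon gamma, -0.19 and -1.01 for MHC class II and I, 2.06 for cholesterol biosynthesis, 0.48 for LXR targets, 0.69 for PPAR targets, 0.96 for fatty acid synthesis, 0.29 for glycolysis, 0.61 for the respiratory chain, 0.82 for the tricarboxylic acid cycle, 0.25 for lysosome, 0.066 for scavenger receptors, -0.093 for complement, -0.92 for chemokines, -0.13 for tumour-promoting factors, 0.10 for extracellular matrix, 0.86 for S phase and mitosis, 0.83 for p53 targets, -0.66 for immediate early genes, 0.47 for hypoxia, 0.95 for ER stress, 1.34 for ATF4 targets, -0.11 for NRF2, 0.76 for heat shock, 0.46 for iron handling, -0.19 for toll-like receptors, 0.25 for feedback genes, 0.56 for ribosomal proteins, 0.26 for macrophage identity, -0.17 for dendritic cells, 0.15 for osteoclasts, 0.35 for stroma, 0 for epithelial and endothelial cells, and -0.10 for progenitors. Signs turned in this setting for the scavenger receptor, extracellular matrix and ribosomal lists, which stood apart, and for 11 lists that did not, LXR targets, glycolysis, lysosome, hypoxia, eicosanoid enzymes, iron handling, feedback genes, macrophage identity, Ly6C monocytes, osteoclasts and stroma.

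With a pseudocount of 0.1 values moved to -7.26 for classical activation, -4.29 for type I interferon, -3.49 for chemokines and -1.13 for tumour-promoting factors. A pseudocount of 5 gave 1.40 for alternative activation, -4.63 for classical activation, -2.78 and -4.71 for type I interferon and interferon gamma, -0.48 for tumour-promoting factors, -0.74 for immediate early genes and -0.70 for toll-like receptors. A larger pseudocount shrinks ratios by construction. The 5 FPKM minimum gave 2.12 for alternative activation, -0.13 for MHC class II and -3.42 for chemokines, and TPM gave -6.58 for classical activation. The cause was not tested for these 4. Genes under the minimum of 1 FPKM entered only without a filter, and no depth replaces a second library per group.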

Other observations

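Beyond the fixed lists, 40 NF-kB and lipopolysaccharide target genes were written down before their values were looked at, and the tests on cells of other types, on the RON kinase and on unequal totals were chosen only after the main result was seen. Of the 40, 39 were at least 2-fold higher in the library labelled WT and 0 in the library labelled RON TK-/-, with a median log2 ratio of -3.52. Icam1, an adhesion receptor, had 1274 FPKM in the library labelled WT against 16.6, the cytokine subunit Il27 116 against 0.22, the NF-kB subunit gene Nfkb2 177 against 15.9 and the interleukin gene Il15 180 against 7.45. The exception was the argininosuccinate synthase gene Ass1 (35.9 against 22.1). These examples were picked after their values were seen.

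Use of transcripts was compared for 565 genes with at least 2 listed transcripts and at least 20 FPKM in both libraries. In 1 of them, the tryptophanyl-tRNA synthetase gene Wars, a transcript's share differed by at least 50 percentage points. The transcript of 2764 bases had 54.9% of the Wars FPKM in the library labelled WT and 0.0030% in the library labelled RON TK-/-, and the transcript of 2831 bases had 38.4% and 94.7%. Shares of transcripts estimated from 50-base single reads are uncertain, and no explanation was tested.

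The first pattern is the high level of inflammatory genes and the low level of Arg1, Chil3, Retnla and most interleukin-4 genes apart by 2-fold in the library labelled WT, which goes against the treatment its label states. Most measured markers of lymphocytes, neutrophils, mast cells and erythroid cells were under 1 FPKM in both libraries. That argues against these cells as the main source of the pattern, and S100a9, Cd3e and Hbb-b1 were listed at 0. The median FPKM of each type's measured markers was at most 0.062 in the library labelled WT. This median followed from so few markers being detected and adds no separate support. Not all markers were low, as 8 of 91 had at least 10 FPKM in each library, while S100a8 had 1.44 and Camp 0.90 in the library labelled WT, and dendritic cells were not part of this test. An inflammatory stimulus or another sample under the WT label, and loss of RON kinase activity alone, cannot be told apart, because there was 1 library per genotype. Mst1r was listed at 0 FPKM in both libraries, so no RON transcript was seen in the library labelled WT, RON proficient. That value bears on the RON explanation but rests on 1 library. The 39 of 40 target genes above describe how broad the profile is and do not separate these explanations. RON is reported in other work to restrain inflammatory activation of macrophages, which would give its loss the opposite direction. Whether that held in these cells was not tested, so it does not decide between these explanations.

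The second pattern is the median log2 ratio of 0.57 over all detected genes. A few abundant genes taking reads from the rest of the library labelled WT do not account for most of it. The median stayed at 0.46 without the 100 most abundant genes of each library (147 genes together). A value above 0.3 had been set as the bound against this explanation. However, the 100 most abundant genes took 28.2% of estimated reads in the library labelled WT and 24.9% in the other. Shares this close left the median little room to fall, so the test adds little beyond them. Transcript length is also argued against, because genes in the lowest and highest tertile of transcript length differed by 0.056 in median ratio (0.57 and 0.52). Genes were also grouped by level, taken as the geometric mean of FPKM + 1 in the libraries, minus 1. The median was 0.72 for genes at 1 to 10 on that scale and 0.31 for those at 100 or more. Detected genes at other levels are in neither group. Unequal totals are argued against as well, since the log2 ratio of total FPKM was only 0.065. The median stayed at 0.55 with each library rescaled to the same total, an outcome that this small difference had fixed in advance. A difference in the number of genes expressed stays open and was not tested. The counts with at least 1 FPKM (9982 and 10911) cannot show it, since a shift of most values alters such counts too.

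The third pattern is the number of genes apart by 2-fold. Genes near the targeted locus could hardly be a main source, as the 200 detected genes around Mst1r are few beside all 11288 detected genes. Of these 200, 32.5% were apart by 2-fold, at percentile 33.2 of 717 other runs of 200 neighbouring genes. Those runs overlapped, so far fewer of them were separate stretches. The percentile shows no excess from DNA of another strain carried along with the locus, but a few such genes could not be seen this way. Animals of different sex are argued against by Xist, with a log2 ratio of 0.38, and by 4 Y-linked genes at 0 in both libraries. The treatment, the genotype and differences between single cultures stay open and could not be tested.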
